A study of Mus musculus with 2 samples.

How the data were processed

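MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured in the striatum of 10-week-old male mice on 3D-Gene mouse miRNA chips. There were 2 arrays, 1 of an R6/2 mouse sample and 1 of a wild-type mouse sample, and the labels do not say how many animals went into either. Per the labels' protocols, total RNA was extracted with TRIzol and labelled with the single dye Hy5, so each array holds 1 sample and 1 colour. The labels say nothing more on pairing or batch.

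The deposited values are linear normalized intensities with 1 decimal, and a blank cell where no value is given. The background correction, the rule for a blank cell and the scaling are not given in the sources used here. In the deposited table each array's intensity has a median of 25 over its own filled cells, so the authors' values appear scaled to that median. The 2 medians were taken over different numbers of filled cells, 1650 in the R6/2 array and 1376 in the wild-type array. One unit of intensity therefore need not stand for the same amount of RNA on both arrays.

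The deposited table has 3200 rows, each named by an identifier of the miRBase mature-miRNA form and by no miRNA name. The identifiers increase by exactly 1 at all 3199 steps from row to row, and the last 1300 rows hold no value in either array. Numbers in the miRBase series are shared among species, so an unbroken run is not what a list of mouse miRNAs would give. It was not possible to tell here which identifiers belong to the miRNA that was measured in their row. The mouse gene table at hand (assembly GRCm38.p6) lists genes and no accessions of this form, so it can neither name the rows nor test the identifiers. Because no table used here pairs the identifiers with names, they are given only as row names, and no miRNA is named. The 18 miRNA lists that had been fixed for this tissue and disease model before the data were examined could not be matched, so 0 list results were computed, and their comparison with 10000 random lists was not run.

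From the deposited intensities the log2 ratio of R6/2 over wild-type was computed for the 1369 rows with a value in both arrays, with no pseudocount. Counts of rows at least 2-fold higher or lower used the 685 rows in the upper 50% by mean log2 intensity. The rule for rows named in the text was also fixed before the data were examined. The part of it applied here took up to 10 rows with the highest ratio and up to 10 with the lowest. They came from these 685 rows and had changed at least 1.5-fold. The other parts of the rule named members of the miRNA lists and could not be applied. Because the names are not paired with the identifiers, only the first 2 in each direction are printed. With 1 array per group no test was run and no p-value is given. Intervals of medians over rows are 95% bootstrap intervals from 10000 draws of rows; rows are not replicates, so these intervals describe this pair of arrays alone. The number of arrays, not the number of rows, limits the precision. The spread of ratios within an intensity class is given as a robust SD, the scaled median absolute deviation.

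The alternatives were centring the ratios on their median, quantile normalization, removal of an intensity trend (lowess, span 0.4), a pseudocount at each array's lower quartile (11.3 for R6/2 and 12.3 for wild-type), other intensity filters and a 1.5-fold limit. With no replicate spread, a ratio was taken as moved by an alternative when it changed by 0.25 or more on the log2 scale, a count when it changed by over 1.5 times and a share when it changed by over 10 percentage points. The counting step was tested on a simulated pair of arrays with the same mean intensities and 1 constant shift of 0.30. Noise was normal, with the robust SD of each row's intensity class, and 200 of the 685 rows were changed, equally many up and down. Equal numbers leave the median ratio almost in place, so the runs do not show how centring behaves when changes are unequal. Neither the fall of the ratio with intensity nor unchanged rows far outside the bulk were simulated. The wrong calls given here therefore do not estimate how many of the real counts are noise. At a 4-fold change the counting step found 100% of the rows in each direction, as deposited and centred. The shift of 0.30 brings a 2.5-fold drop close to the 2-fold limit on the deposited scale, so many such rows were bound to be missed. At a 2.5-fold change the counting step found 100% of the higher and 54% of the lower rows on the deposited scale, and 87% and 90% after centring. On the deposited scale it also called as higher 2 rows that had not been raised at the 2.5-fold setting and 1 at the 4-fold setting, and after centring 0 at either; it called 0 rows wrongly as lower in all 4 runs. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.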

Results

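The miRNA content of the striatum was profiled in R6/2 and wild-type mice at 10 weeks of age. R6/2 mice carry a transgene with the first exon of the human huntingtin gene and an expanded CAG repeat, and are a widely used model of Huntington's disease, in which the striatum is the most affected brain region. There was 1 array per genotype, both from males. No value below has a replicate error, and each difference is a difference between 2 arrays. The rows carry identifiers that could not be tied to miRNA names, so the results are given per row.

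The R6/2 array had a value in 1650 rows, with intensities from 3.6 to 131208. The wild-type array had a value in 1376 rows, with intensities from 4.7 to 112973. Of the 1900 rows up to the last filled one, 1369 had a value in both arrays, 281 in the R6/2 array alone, 7 in the wild-type array alone and 243 in neither. Signal was concentrated in few rows in both genotypes. The 3 brightest rows held 37.3% of the summed intensity in R6/2 striatum and 36.0% in wild-type striatum, and the 10 brightest held 53.9% and 54.1%. The 10 brightest rows of the 2 arrays had 9 rows in common.

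The comparison asked which miRNAs differ in level between R6/2 and wild-type striatum. The 2 profiles were close. Across the 1369 shared rows, log2 intensities had a Pearson correlation of 0.984 and intensities a Spearman correlation of 0.966; these are correlations across rows of 1 pair of arrays, and rows are not independent replicates. Among the 685 brighter rows, 613 (89.5%) lay within 1.5-fold of the overall shift described next.

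Over the shared rows, deposited intensities were mostly higher in the R6/2 array. The median log2 ratio over the shared rows was 0.30, a 1.23-fold difference, and 1154 rows had a ratio above 0 against 210 below. The median ratio was 0.45 (95% bootstrap interval over rows 0.38 to 0.52) in the dimmest 342 rows and 0.21 (0.18 to 0.23) in the brightest 343. Each array's median over its own filled rows was 25, and over the shared rows the median was 33.5 for R6/2 and 25.3 for wild-type. The 281 rows filled in R6/2 alone all lay below 25, so leaving them out could only raise the R6/2 median. Ratios are given below both as deposited and relative to the median ratio. Of the 685 brighter rows, 82.2% were higher in R6/2 as deposited and 37.7% relative to the median ratio, so the direction of small differences depended on the scale.

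Among the 685 brighter rows, 21 were at least 2-fold higher and 5 at least 2-fold lower in R6/2 striatum as deposited. Relative to the median ratio, 14 were higher and 8 lower. The second pair of counts follows from taking the same constant, 0.30, off every log2 ratio. In the brightest 343 rows 7 were higher and 5 lower as deposited, and 4 higher and 7 lower relative to the median ratio. The scale thus decided which direction was more frequent there. The constant of 0.30 is larger than the median ratio of these brightest rows, 0.21, so taking it off tilts their counts toward lower. The robust SD of the log2 ratio was 0.22 in these brightest rows and 0.51 in the dimmest 342, so a 2-fold difference stood further outside the bulk of the rows at high than at low intensity.

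The lowest ratio belonged to the row MIMAT0000144, with an intensity of 406.7 in R6/2 and 1238.9 in wild-type striatum. Its log2 ratio was -1.61 as deposited, 3.05-fold lower in R6/2, and -1.91 relative to the median ratio. The row MIMAT0000269 followed, with 132.2 in R6/2 and 365.6 in wild-type, a log2 ratio of -1.47 as deposited and -1.77 relative to the median ratio. The 10 lowest of the 685 brighter rows spanned log2 ratios of -1.61 to -0.62 as deposited. By mean log2 intensity, 9 of the 10 were in the brightest 343 rows. Their median intensity was 268.8 in R6/2 and 476.3 in wild-type striatum. As deposited 5 of these 10 passed 2-fold. Relative to the median ratio 8 did, which follows from the constant taken off every ratio.

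The highest ratio in the brighter rows belonged to MIMAT0000798, with an intensity of 137.6 in R6/2 and 24.5 in wild-type striatum. Its log2 ratio was 2.49 as deposited, 5.62-fold higher in R6/2, and 2.19 relative to the median ratio. The row MIMAT0000385 had 115.9 in R6/2 and 26.2 in wild-type, a log2 ratio of 2.15 as deposited and 1.84 relative to the median ratio. The 10 highest rows spanned log2 ratios of 1.48 to 2.49 as deposited. All 10 also passed 2-fold relative to the median ratio, which follows from the size of the constant, since the lowest was then 1.17. Their median intensity was 126.8 in R6/2 and 25.6 in wild-type striatum, and 4 of the 10 lay in the brightest 343 rows by mean log2 intensity. The lowest wild-type value among them was 16.6, between the wild-type array's lower quartile of 12.3 and its median of 25. Some of these folds therefore rest on a low wild-type intensity.

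**Figure D1:**
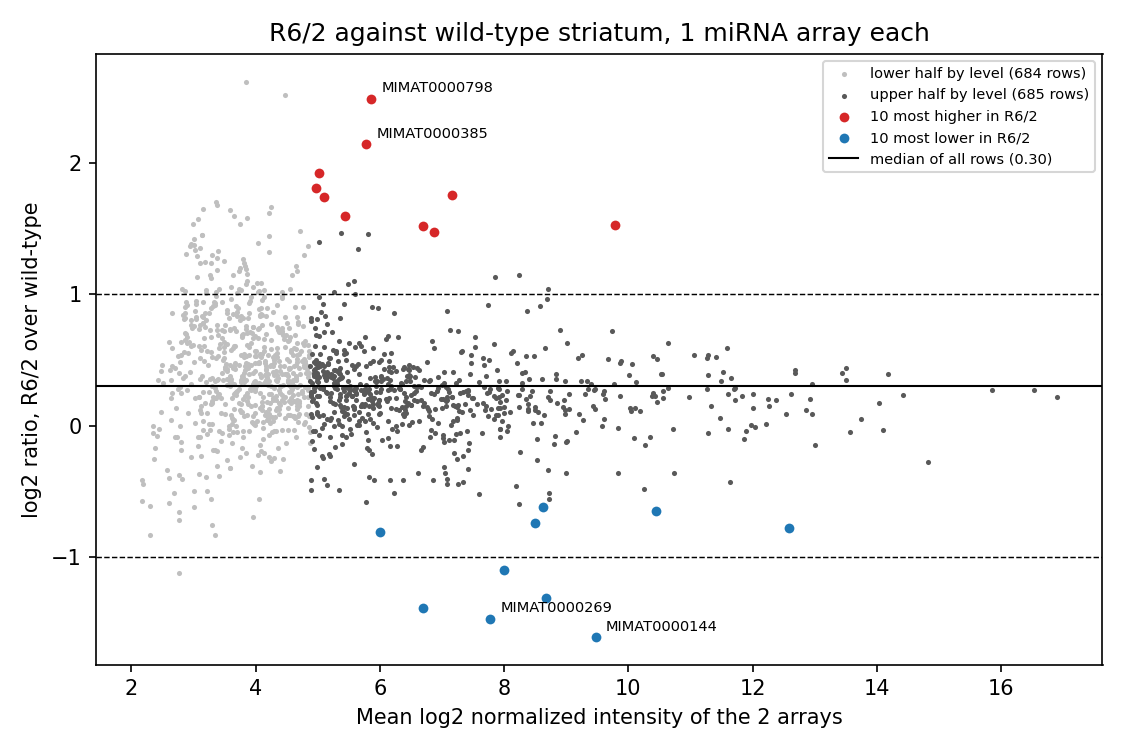
Log2 ratio of R6/2 over wild-type intensity (vertical axis) against the mean log2 intensity of the 2 arrays (horizontal axis), 1 point per row with a value in both; the solid line is the median ratio of 0.30, the dashed lines mark 2-fold differences, and the coloured points are the 10 highest and 10 lowest rows of the 685 brighter ones. Most of the cloud lies above 0 and it narrows toward high intensity, and the 10 lowest rows sit at higher intensity than most of the 10 highest.

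The 10 rows with the highest mean log2 intensity all lay within 2-fold between the arrays. Their log2 ratios lay between -0.28 and 0.39 as deposited, with 7 above 0 and 3 below. Relative to the median ratio they lay between -0.58 and 0.09, with 1 above 0 and 9 below.

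The rows with a value in 1 array alone were dim. The 281 rows with a value in R6/2 alone had intensities from 3.6 to 18.5, with a median of 6.1, and the 7 rows with a value in wild-type alone had intensities from 4.8 to 8.0. No fold is given for them, because the meaning of a blank cell is not given in the sources used here.

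**Figure D2:**
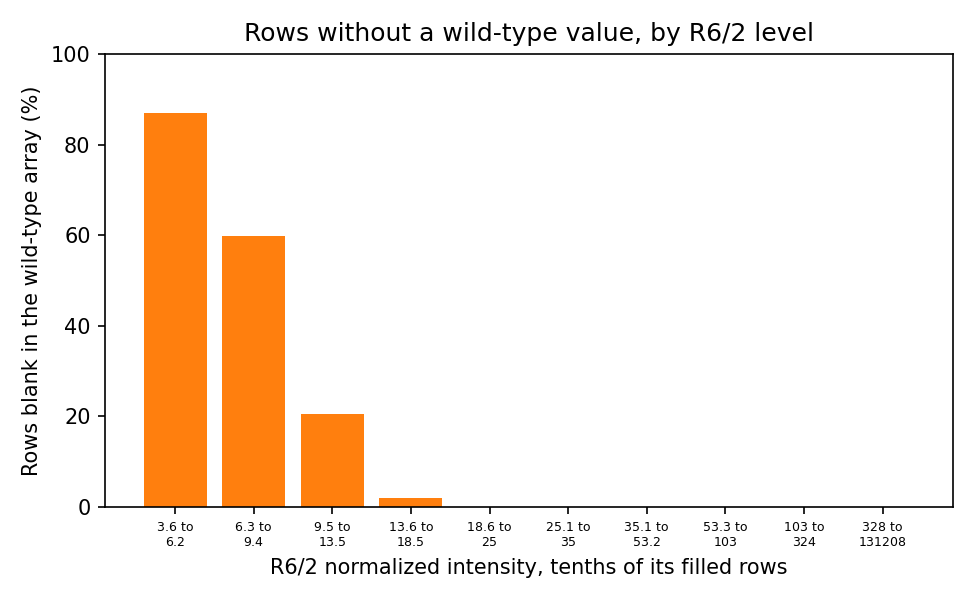
Share of rows with a blank cell in the wild-type array, in percent (vertical axis), for the rows filled in the R6/2 array, divided into 10 classes of rising R6/2 intensity (horizontal axis, with each class's range). The share is 86.9% in the dimmest class and 0% from the fifth class up.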

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

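All tests in this part were chosen after the values they use had been seen. In the R6/2 array 281 rows held a value that the wild-type array left blank, against 7 rows the other way, and the comparison of ratios uses none of them. All 281 lay below the median intensity of 25, the highest at 18.5 and the median at 6.1, and 278 of them fell in the lowest 3 of 10 classes of R6/2 intensity. The share of rows blank in wild-type went from 86.9% in the lowest class to 59.8%, 20.4% and 1.8% in the next ones and was 0% from the fifth class up. Wild-type values lost near a detection limit would give such a fall. Any other cause that left only dim rows blank would give it too, so it cannot tell them apart. The wild-type array held values down to 4.7. Yet 98 rows at R6/2 intensities of 6.3 to 9.4 and 34 at 9.5 to 13.5 were blank in it. A limit as the cause would thus have to act more strongly on the wild-type array. The highest R6/2 intensity involved was 18.5, so no bright row was seen in R6/2 alone. An effect of genotype on these dim rows stays open, since 1 array per group cannot separate it from the array.

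The second pattern is the median log2 ratio of 0.30 over the shared rows. One scaling factor as the whole cause is argued against, because the dimmest rows had a median ratio 0.25 higher than the brightest (95% bootstrap interval over rows 0.17 to 0.32) and 1 factor would move both alike. Leftover background in the R6/2 array as the whole cause is argued against too, because the brightest 343 rows still had a median ratio of 0.21 (0.18 to 0.23). A mixture of both remains open. So does the size of the part played by medians set over different numbers of filled rows. Both full medians are 25, and the 281 rows filled in R6/2 alone all lay below 25. Leaving them out could only raise the R6/2 median over the shared rows, which was 33.5 against 25.3 for wild-type. Over its brightest 1376 rows the R6/2 median exceeded the wild-type median by 0.41 on the log2 scale. The sign of this difference was fixed in advance, because both full medians are 25, so it does not settle how large that part is. Genotype stays open too, since 1 array per group cannot separate it from the array.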

How the results depend on the processing

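With 1 array per group no replicate could be left out, and no paired analysis was possible because each group has a single array. The list results were not run, since no row could be tied to a miRNA name. The count of rows at least 2-fold higher in R6/2, 21 as deposited, was 92 with no filter on intensity, 7 in the upper 25% by mean intensity and 69 at 1.5-fold. It was 14 under centring, quantile normalization and trend removal alike, 16 with the pseudocount and 30 with the upper 50% taken by the higher array. The count of rows at least 2-fold lower, 5 as deposited, was 8 after centring and 11 at 1.5-fold, and lay between 5 and 6 under the other single changes. In combinations chosen after seeing the data, centring gave 29 higher and 43 lower rows at 1.5-fold, against 69 and 11 as deposited. The more frequent direction thus turned. The 0.30 taken off is larger than the median ratio of these 685 rows, 0.24, which tilts their counts toward lower. Centring gave 41 higher and 13 lower with no filter on intensity, against 92 and 6 as deposited, and 4 higher and 7 lower in the upper 25%, against 7 and 5. The share of the 685 brighter rows with a higher value in R6/2, 82.2% as deposited, turned to 37.7% after centring and 47.2% after quantile normalization and was 51.2% after trend removal; each of these sets the overall ratio near 0 by construction. The median ratio of 0.30 was 0.19 with the pseudocount, and, in alternatives added after seeing the data, 0.24 in the brighter 685 rows and 0.21 in the brightest 343. The 4 printed rows kept their direction in all 16 alternative values, of which 10 moved by 0.25 or more. The low intensity of many rows limits the ratios below the brighter 685, where the robust SD reached 0.51.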

Other observations

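Neighbouring rows of the table had slightly similar ratios. After removal of the intensity trend, the log2 ratios of adjacent rows had a Pearson correlation of 0.091 and a Spearman correlation of 0.081 over 1031 adjacent pairs, which are pairs of rows within 1 pair of arrays and not replicates. In 10000 shuffles of the row order, 95% of the Pearson values lay between -0.061 and 0.061. This relation was looked for after the ratios had been seen, and no explanation for it was tested.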
